A study of Mus musculus with 16 samples.

How the data were processed

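RNA-seq libraries of mouse E14Tg2a.IV ES cells were made from total RNA with an Illumina TruSeq RNA kit, per the labels; how messenger RNA was enriched is not stated there. The submitters' processing notes name FastQC 0.11.5, Bowtie2 2.3.3, SAMtools 1.9, featureCounts 2.0.1 and DESeq2 and the genome build mm10 for every sample, without saying what each tool did; whether counting used strand is not given in the sources used here. The authors deposited 3 tables of normalised values with 1 column per library. The Pml table holds FPKM values (read fragments scaled for transcript length and library size), as deposited by the authors under that name. The arsenite table holds RPKM values (reads scaled for gene length and library size), as deposited under that name. The Trim33 table names no unit; its deposited values behave as RPKM, because a value times the annotated length of a single-exon gene falls on whole multiples of 1 read as in the arsenite table. No column other than those of the 16 libraries held values. Columns were matched to samples by name, and groups and replicate numbers were taken from the sample titles. The untreated cells' columns carry another letter than their titles and were matched as the remaining untreated group of that table.

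Depth was recovered from the low values of 2281 single-exon genes: values worth under 20 reads were whole within 0.05 reads for 90.6% to 94.4% of cases in the RPKM tables, which gives 48500000 and 47800000 reads for untreated and 46800000 and 47900000 for arsenite. In the Trim33 table it gives 34700000 and 38600000 for the libraries labelled knockout with activin A, 32000000 and 33500000 for knockout with SB431542, 33200000 and 31200000 for wild type with activin A, and 39500000 and 34900000 for wild type with SB431542. A value of 1 RPKM is thus 31.2 to 48.5 reads per kilobase of gene. In the Pml table only 14.7% to 20.6% were whole, so its depth is unknown. No library pair of a group held identical values. Over genes with at least 10 reads, the chi-square per degree of freedom between replicates was 4.06 in arsenite and 4.96 in untreated. It was 13.7 to 22.1 in the Trim33 table. These values exceed the 1 of sampling noise, which separate preparations of the same culture could also do. The Pml table could not be tested this way. Each library was counted as 1 replicate.

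Values were tested on the log2(value + 1) scale, which understates the change of low genes. Genes with a value of at least 1 in at least 2 libraries of a table were kept, after leaving out 27 date-like names per table (of 24347 names in the Pml table and 24421 in the others) that a spreadsheet had made from gene symbols. A gene under 1 throughout a group was thus tested only where other libraries reached 1. For lists of low genes this favours calls toward the group where they were high. R 4.3.3 and limma 3.58.1 were used (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment over all genes tested, a call at adjusted p under 0.05). The Pml and arsenite tables were fitted alone (4 libraries, 2 residual degrees of freedom each) and the Trim33 table as 4 group means (8 libraries, 4 residual degrees of freedom). The values are not counts, so no count-based test was run. With 2 libraries per group, replicate error rests on the spread that limma shares between genes. Fold changes are log2 differences of group means with their standard errors, and levels are means ± SD of the deposited values.

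Gene groups were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists with at least 3 tested members, and again with an estimated correlation. There were 32 lists, covering signalling targets, stress responses, cell type markers and RNA classes, and 31, 30 or 31 of them could be tested in the Pml, arsenite and Trim33 tables. Overlaps were tested with Fisher's exact test with 95% intervals. Groups, tests, lists and alternatives were fixed before the data were examined, except for the mean activin A effect over both genotype labels, the test of directions among genes called in both knockouts, and the tests of what lies behind the SB431542 libraries and the marker lists of the Pml knockout. Named genes are Pml, Trim33, Lefty1 and Lefty2, the 8 called genes with the largest rise and the 8 with the largest fall whose groups do not overlap (leaving out numbered Gm names, Rik and LOC names, and those marked as pseudogenes), and up to 4 members of a list with the smallest p; fewer were used, from the top of each ranking.

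Coordinates and exon numbers come from GENCODE annotation of GRCm38, the same assembly as mm10. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for depth, annotation and figures. The fits were tested on simulated data made from the real means with 200 changed genes in 10 draws. With the spread drawn from limma's prior, 80.7%, 99.0% and 99.8% of genes changed by 1.5, 2 and 4-fold were recovered in the Pml comparison over 11429 genes, and 5.10% of its calls were false. In the arsenite comparison over 11836 genes, 86.7%, 99.2% and 100% were recovered and 4.42% of calls were false. In the Trim33 comparison with activin A over 11605 genes, 7.81%, 60.8% and 94.1% were recovered and 4.81% were false. For activin A over both labels, over 11606 genes, 41.9%, 89.6% and 99.4% were recovered and 4.41% were false. With each gene's spread set to its moderated estimate instead, the false share rose to 10.2% and 9.99% in the Pml and arsenite comparisons and 6.70% and 5.99% in the others, above the nominal 5%. A changed list was called in 10 of 10 draws in each comparison, and unchanged lists in 12 of 300 tests for Pml, 0 of 290 for arsenite, 6 of 299 for Trim33 and 2 of 299 for activin A over both labels. Errors were drawn independently for each gene, so these rates do not show how the list test behaves when members vary together.

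Alternatives were a pseudocount of 0.1, no filter, a filter of 5, TMM-scaled values, quantile normalization, no trend in the variance, the replicate number as a block, a 2-fold minimum, an estimated correlation for the lists, fits of only the 2 groups compared, and each library left out. The tables hold no mitochondrially encoded genes, so that list has no result.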

Results

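RNA-seq libraries were examined from mouse embryonic stem (ES) cells of the E14Tg2a.IV line, grown without feeder cells in medium with serum and LIF. The growth protocol also names the CCE line, without saying which samples it concerns. The series title names PML nuclear bodies, TRIM33 and the genes Lefty1 and Lefty2. PML is the scaffold protein of the nuclear bodies that carry its name, TRIM33 is a chromatin-bound TIF1-family protein that can join SMAD2 and SMAD3, and Lefty1 and Lefty2 encode secreted inhibitors of Nodal. There were 16 libraries in 8 groups of 2, held in 3 separately normalised tables, so values were tested only within a table. One table held wild-type and Pml-knockout cells. The second held untreated cells and cells given 200 µM sodium arsenite, an oxidative and proteotoxic stressor, for 2 h. The third held cells labelled wild type or Trim33 knockout, given either 50 ng/ml activin A, a ligand that activates SMAD2 and SMAD3, or 10 µM SB431542, an inhibitor of its type I receptors, for 2 h. Recovered depth was 46800000 to 48500000 reads per library in the arsenite table and 31200000 to 39500000 in the Trim33 table. It is unknown for the Pml table. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

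In the Pml table, Pml itself fell in the knockout but was not lost: 47.5 ± 3.39 FPKM in wild type and 32.8 ± 1.04 in knockout (SD, n = 2 each), a log2 fold change of -0.52 ± 0.06 (SE, adjusted p = 4.89e-04). The single libraries read 49.8 and 45.1 FPKM in wild type and 32 and 33.5 in knockout, so the direction followed the labels. Pml lies on chromosome 9, positions 58218076 to 58249786 on the minus strand (GRCm38), with 9 exons in its longest transcript. The values give 1 number per gene and do not show whether the remaining transcript lacked an exon.

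In the Trim33 table, Trim33 went against the genotype label in every SB431542 library. The libraries labelled wild type with activin A read 20.1 and 23.5 RPKM and those labelled knockout with activin A read 2.53 and 2.79. With SB431542, the libraries labelled wild type read 2.94 and 2.44 RPKM and the libraries labelled knockout read 18.3 and 24.6. Trim33 lies on chromosome 3, positions 103279293 to 103358775 on the plus strand, with 20 exons in its longest transcript. Eif2s3y, a Y-linked translation factor gene, followed the same arrangement: 39.7 ± 1.9 RPKM in libraries labelled wild type with activin A, 0.0325 ± 0.0460 in those labelled knockout with activin A, 0.143 and 0.0647 in those labelled wild type with SB431542, and 40.0 and 38.5 in those labelled knockout with SB431542 (SD, n = 2). Every direction between genotype labels with SB431542, or between treatments within a genotype label, therefore rests on a label that Trim33 contradicts, and those libraries are called by their labels throughout.

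**Figure D1:**
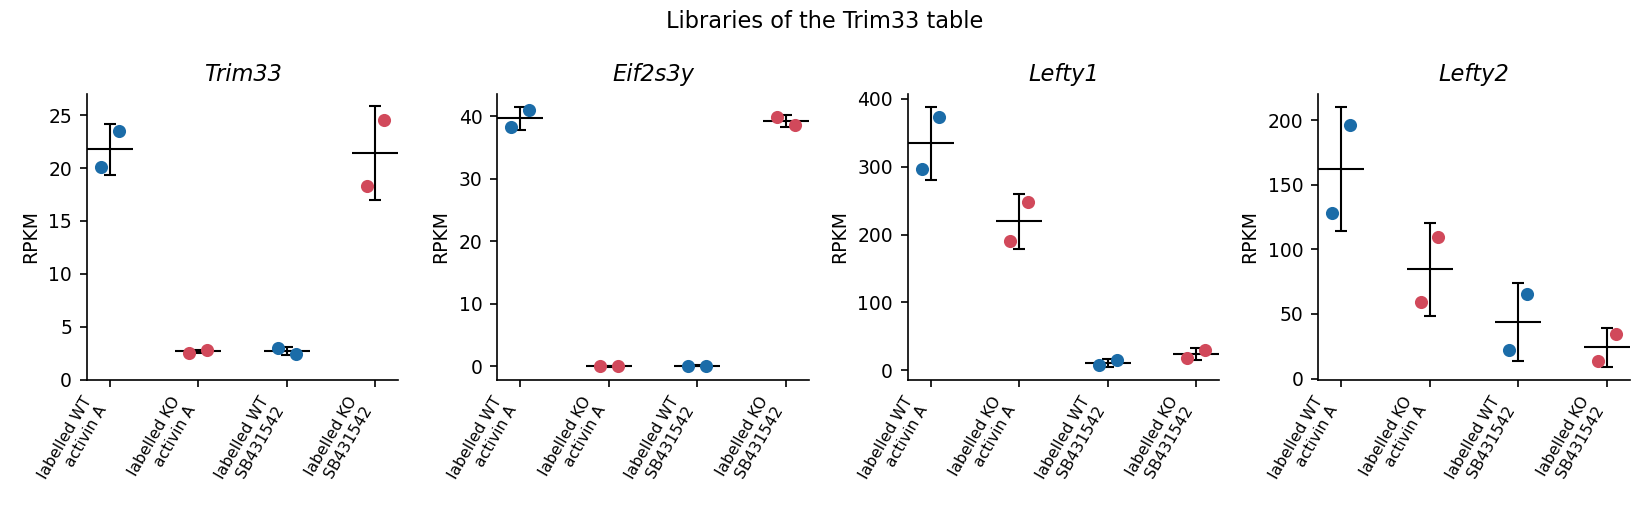
RPKM of Trim33, Eif2s3y, Lefty1 and Lefty2 in each of the 8 libraries of the Trim33 table (dots), with the mean and SD of each labelled group (lines). Trim33 lay between 2.44 and 2.94 RPKM in the libraries labelled knockout with activin A and wild type with SB431542, and between 18.3 and 24.6 in the others.

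The comparison of Pml-knockout with wild-type ES cells asked which genes, Lefty1 and Lefty2 among them, depend on PML. The Y-linked genes Eif2s3y (18.4 FPKM in wild type and 0.927 in knockout), Ddx3y (4.19 and 0.196) and Uty (1.87 and 0.0522) also differed. Another difference between the cell lines than Pml therefore cannot be told apart from the knockout in any result of this comparison. Lefty1 fell from 71.9 ± 8.59 to 45.6 ± 0.175 FPKM and Lefty2 from 72.3 ± 1.46 to 43.9 ± 2.59 (SD, n = 2), log2 fold changes of -0.64 ± 0.08 and -0.71 ± 0.06 (SE, adjusted p = 4.00e-04 and 4.64e-05). The largest rises were in Igf2, an imprinted growth factor gene (2.45 ± 0.264 to 101.5 ± 3.45 FPKM), Tagln, which encodes an actin-binding protein of smooth muscle (9.52 ± 1.35 to 271 ± 10.4), and the simple-epithelium keratin genes Krt18 (11.8 ± 0.736 to 280 ± 2.28) and Krt8 (18 ± 0.653 to 323 ± 10.5). Pmp22, which encodes a myelin membrane protein, rose by 4.15 ± 0.08 on the log2 scale, Acta2, the smooth-muscle actin gene, by 4.02 ± 0.09, Vgf, a neuropeptide precursor gene, by 3.64 ± 0.10, and Acta1, the skeletal-muscle actin gene, by 3.57 ± 0.09. The largest falls were in Snora16a, a small nucleolar RNA listed at 0 in both knockout libraries and at 347 ± 98.3 FPKM in wild type, Eif2s3y (-3.33 ± 0.13), the imprinted adaptor gene Grb10 (-3.11 ± 0.09), Ubap1l (-3.03 ± 0.10), the ATP-gated channel gene P2rx3 (-2.92 ± 0.11) and G0s2, which encodes an inhibitor of fat breakdown (-2.81 ± 0.17). Trim33 stood at 14.0 ± 0.319 FPKM in wild type and 14.1 ± 0.267 in knockout (0.01 ± 0.07, adjusted p = 0.895).

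Marker genes of several other cell types rose in the Pml knockout. Of 11 trophectoderm genes tested, 9 rose and 1 fell (all 11 passed when adjusted over the list alone): Krt19 rose by 3.45 ± 0.08 and Cdx2, a transcription factor gene of the trophectoderm, by 3.07 ± 0.10, beside Krt8 and Krt18 above. The camera test placed the list above other genes (adjusted p = 1.17e-08, but adjusted p = 0.254 with an estimated correlation). That second value decides little, because with 2 residual degrees of freedom 0.254 was the lowest that camera gave over all 31 lists. Of 11 fibroblast markers, 10 rose and 1 fell (11 adjusted over the list alone). Among them were Tagln, Acta2, the collagen gene Col1a1 (3.16 ± 0.11) and the intermediate filament gene Vim (1.34 ± 0.05). The camera test gave adjusted p = 1.17e-08, and adjusted p = 0.254 with an estimated correlation. All 9 tested genes of the two-cell-like state rose (9 adjusted over the list alone). They included Zscan4a (1.43 ± 0.10), Zscan4c (1.38 ± 0.11) and Gm2016 (1.33 ± 0.10), from wild-type means of 0.689 to 1.51 FPKM. Camera gave adjusted p = 8.50e-08, and adjusted p = 0.273 with an estimated correlation. Of 6 mesoderm and definitive endoderm genes, 4 rose (4 adjusted over the list alone). Examples were the primitive-streak genes T (2.27 ± 0.09) and Wnt3 (2.31 ± 0.11). Its camera adjusted p was 0.00590, and adjusted p = 0.273 with an estimated correlation.

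Stress and growth-control genes split by pathway. Of 19 p53 targets, 15 rose (16 adjusted over the list alone). Among them were the membrane protein gene Perp (1.99 ± 0.06), the kinase gene Plk2 (1.88 ± 0.07), the cyclin gene Ccng1 (1.12 ± 0.05) and the cell-cycle inhibitor gene Cdkn1a (1.21 ± 0.06). For this list camera gave adjusted p = 1.17e-08, and adjusted p = 0.254 with an estimated correlation. Of 14 immediate early genes, 11 rose and 2 fell (13 adjusted over the list alone). They included Jun at 2.25 ± 0.09, Klf6 at 1.19 ± 0.07 and Egr1 at 0.89 ± 0.07. By camera the list had adjusted p = 1.29e-05, and adjusted p = 0.254 with an estimated correlation. Of 21 targets of ATF4, the transcription factor of the integrated stress response, 16 fell (16 adjusted over the list alone): Chac1, which encodes a glutathione-degrading enzyme (-1.95 ± 0.07), Trib3 (-1.37 ± 0.06) and the mitochondrial one-carbon enzyme genes Shmt2 (-1.04 ± 0.05) and Mthfd2 (-1.02 ± 0.05). Camera gave adjusted p = 5.59e-09 for that list, and adjusted p = 0.254 with an estimated correlation. Of 17 NRF2 antioxidant targets, 10 fell (11 adjusted over the list alone). Examples were the glutathione reductase gene Gsr (-0.71 ± 0.06) and the heme oxygenase gene Hmox1 (-0.66 ± 0.06). By camera the list had adjusted p = 0.00357, and adjusted p = 0.254 with an estimated correlation. Of 13 interferon-response genes, 7 rose (7 adjusted over the list alone). Among them were B2m (1.95 ± 0.07) and Isg15 (1.47 ± 0.12). Its camera adjusted p was 0.00233, and adjusted p = 0.254 with an estimated correlation.

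The pluripotency and Nodal groups went both ways. Of 10 core pluripotency genes, 3 fell, Utf1 first (-0.41 ± 0.05), and 1 rose (4 adjusted over the list alone; camera adjusted p = 0.228). Of 15 naive pluripotency genes, 7 fell and 2 rose (10 adjusted over the list alone). They included Klf5 at -0.81 ± 0.08 and Gbx2 at -0.56 ± 0.05. The list had camera adjusted p = 0.0382, and adjusted p = 0.368 with an estimated correlation and 0.154 with quantile normalization. Of 11 targets of Nodal and activin signalling, 4 rose and 3 fell (9 adjusted over the list alone): beside the fall of Lefty1 and Lefty2, the EGF-CFC co-receptor gene Tdgf1 fell by 0.38 (camera adjusted p = 0.260). In total 4130 of 11648 genes passed in limma, 1931 higher and 2199 lower, of which 451 changed at least 2-fold. For each gene given a direction here, both libraries of one group lay beyond both of the other, which chance alone gives in 33.3% of genes. Eif2s3y, which is Y-linked, moved with the genotype, and 50.72% of the 50-base words of Zscan4a also occur in Zscan4c, so reads can be shared.

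**Figure D2:**
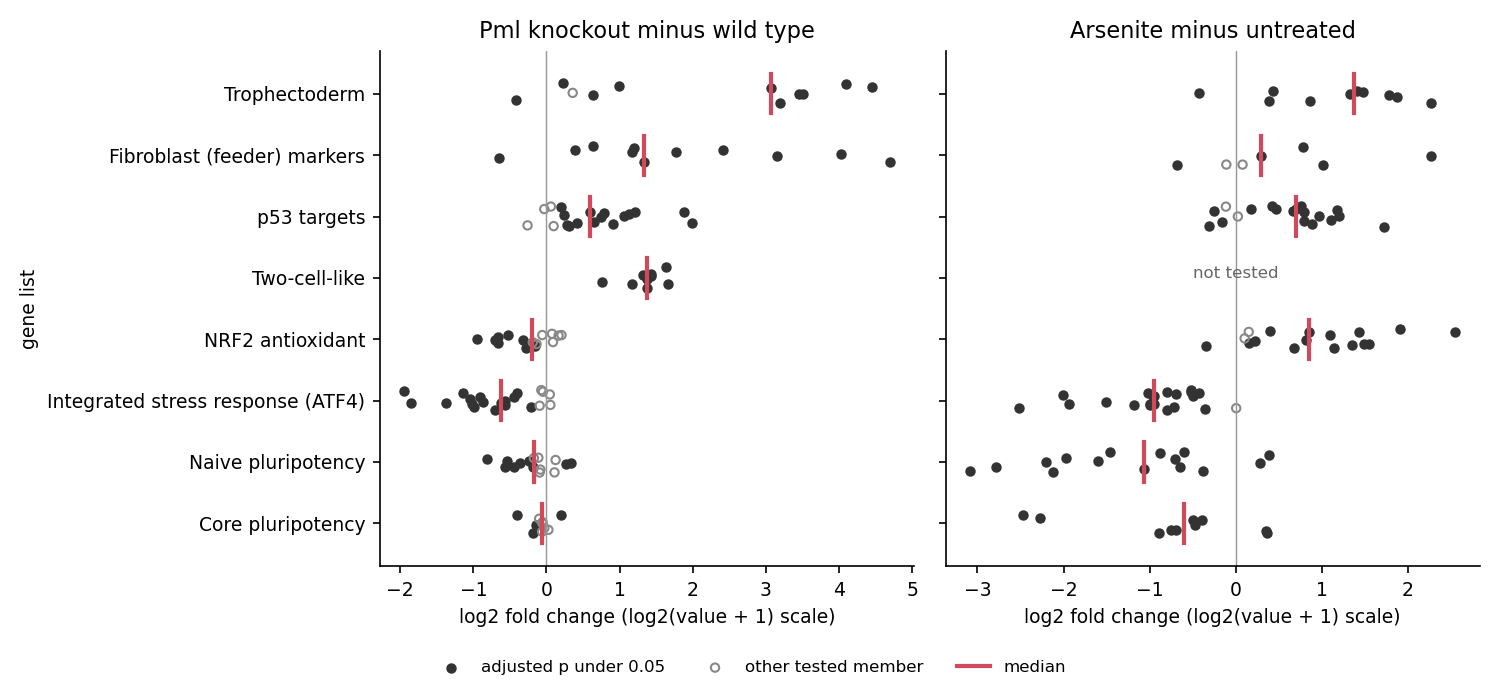
Log2 fold change on the log2(value + 1) scale of each tested member of 8 gene lists (dots, filled where adjusted p was under 0.05, with the list median as a bar) in the Pml knockout against wild type and in arsenite against untreated cells, 2 libraries per group. The trophectoderm medians were 3.07 and 1.37, and those of the integrated stress response were -0.63 and -0.95.

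The arsenite comparison asked how ES cells respond to a stressor that acts on PML. Lefty2 fell from 76.5 ± 5.65 to 10.7 ± 0.0331 RPKM and Lefty1 from 98.9 ± 8.53 to 35.8 ± 0.993 (SD, n = 2), log2 fold changes of -2.73 ± 0.06 and -1.44 ± 0.06 (SE, adjusted p = 1.62e-07 and 1.45e-06). The iron exporter gene Slc40a1 (0.742 ± 0.123 to 24.8 ± 0.368 RPKM), the FGF carrier gene Fgfbp1 (5.38 ± 0.897 to 82.2 ± 2.90), the hormone gene Sct (3.19 ± 0.10), the synaptotagmin gene Syt13 (3.15 ± 0.10) and the imprinted gene Peg10 (37.7 ± 1.12 to 309 ± 15.0) rose most. The largest falls were in Ndufa4l2, a hypoxia-induced mitochondrial gene (-3.22 ± 0.13), the germline and pluripotency regulator gene Prdm14 (-3.09 ± 0.08), the junction gene Jam2 (-2.94 ± 0.05), the WNT inhibitor gene Sfrp1 (-2.89 ± 0.08) and the pluripotency factor gene Klf4 (-2.79 ± 0.05). Pml (52.7 ± 1.80 to 51.7 ± 0.285 RPKM, adjusted p = 0.564) and Trim33 (15.5 ± 0.912 to 14.1 ± 0.802, adjusted p = 0.122) did not pass. Trim33 passed with TMM-scaled values (-0.28, adjusted p = 0.00527) and with quantile normalization (-0.22, adjusted p = 0.0198). Pml passed with TMM-scaled values (-0.19, adjusted p = 0.00707) but not with quantile normalization (adjusted p = 0.868).

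Pluripotency genes fell together. Of 15 naive pluripotency genes, 13 fell and 2 rose (15 adjusted over the list alone). Examples were Zfp42 (-2.13 ± 0.04) and Nr0b1 (-1.46 ± 0.04). Of 10 core pluripotency genes, 8 fell and 2 rose (10 adjusted over the list alone). Among them were Nanog at -2.47 ± 0.06, Fgf4 at -2.28 ± 0.05, Sox2 at -0.89 ± 0.04 and Pou5f1 at -0.75 ± 0.05. For the naive and core lists camera gave adjusted p = 2.52e-07 and 7.48e-04, and adjusted p = 0.390 and 0.436 with an estimated correlation. Of 10 Nodal and activin targets, 5 fell and 3 rose (8 adjusted over the list alone; camera adjusted p = 0.197): Tdgf1 fell by 2.48 while Eomes, a T-box gene of mesendoderm, rose (1.83 ± 0.08). Of 10 trophectoderm genes, 9 rose and 1 fell (10 adjusted over the list alone). They included Krt19 at 1.87 ± 0.06, Krt8 at 1.48 ± 0.05 and Krt18 at 1.41 ± 0.05. With camera this gave adjusted p = 0.00388, and adjusted p = 0.390 with an estimated correlation.

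Oxidant-defence genes rose while ATF4 targets and glycolysis fell. Of 17 NRF2 targets, 14 rose and 1 fell (15 adjusted over the list alone). Examples were the quinone reductase gene Nqo1 (2.55 ± 0.06), the glutathione synthesis gene Gclm (1.91 ± 0.06) and the ferritin heavy chain gene Fth1 (1.43 ± 0.04). The list had camera adjusted p = 4.70e-05, and adjusted p = 0.390 with an estimated correlation. The metallothionein genes Mt1 (211 ± 30.5 to 968 ± 64.3 RPKM) and Mt2 (458 ± 38.9 to 1478 ± 87.8) rose, with 3 of 4 members of the metal-response list up (3 adjusted over the list alone; camera adjusted p = 0.0555, and 0.0252 with TMM-scaled values and 0.0326 with quantile normalization). Of 19 heat-shock genes, 13 rose and 2 fell (15 adjusted over the list alone). Among them were the small heat-shock protein genes Hspb8 at 1.10 ± 0.05 and Hspb1 at 0.69 ± 0.04 and the co-chaperone gene Dnajb1 at 0.73 ± 0.05. The camera test gave adjusted p = 0.00526, and adjusted p = 0.390 with an estimated correlation. Of 19 p53 targets, 14 rose and 3 fell (17 adjusted over the list alone). They included Perp at 1.72 ± 0.06, Ccng1 at 1.18 ± 0.04 and the p53 ubiquitin ligase gene Mdm2 at 0.97 ± 0.04. Its camera adjusted p was 0.00301, and adjusted p = 0.390 with an estimated correlation.

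Of 21 ATF4 targets, 20 fell and none rose (20 adjusted over the list alone). Examples were the stress-response gene Nupr1 (-2.52 ± 0.04), Chac1 (-2.01 ± 0.04), the mTOR inhibitor gene Ddit4 (-1.94 ± 0.05) and Mthfd2 (-1.51 ± 0.03). With camera this gave adjusted p = 2.57e-12, and adjusted p = 0.390 with an estimated correlation. Of 12 genes of the endoplasmic reticulum unfolded protein response, 10 fell and 1 rose (11 adjusted over the list alone). Herpud1, which encodes a membrane protein of that organelle, was at -1.17 ± 0.05. For this list camera gave adjusted p = 1.10e-04, and adjusted p = 0.390 with an estimated correlation. Of 14 hypoxia and glycolysis genes, 12 fell (12 adjusted over the list alone). They included Hk2 at -1.23 ± 0.04, Ldha at -1.14 ± 0.04 and Pgk1 at -1.07 ± 0.04. By camera the list had adjusted p = 2.52e-07, and adjusted p = 0.390 with an estimated correlation. Of 80 cytosolic ribosomal protein genes, 73 fell and none rose (73 adjusted over the list alone). Examples were Rps29 at -1.88 ± 0.10 and Rpl35a at -0.89 ± 0.04. With quantile normalization 44 fell and 12 rose. Camera gave adjusted p = 1.03e-16, and adjusted p = 0.436 with an estimated correlation. In total 8221 of 12136 genes passed in limma, 4939 higher and 3282 lower, with 876 changed at least 2-fold. TMM scaling shifted the median of all genes by 0.14 on the log2 scale, from 0.08 to -0.06, and gave 3460 higher and 4784 lower (42.0% higher against 60.1%). Quantile normalization gave 3833 and 3982 (49.0% higher), so the balance of directions over all genes depends on the scaling.

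The calls of the Pml knockout and of arsenite, which share no libraries, overlapped in both directions. Among 11162 genes tested in both, 1102 rose in both where 683 would be shared by independent lists (odds ratio 3.24, 95% interval 2.91 to 3.61, Fisher's exact test, two-sided, p = 1.56e-108). In the other direction 940 fell in both where 603 would be shared (odds ratio 2.42, 2.19 to 2.67, Fisher's exact test, p = 5.12e-68). Of 2883 genes called in both, 2042 had the same direction, Lefty1, Lefty2, Krt8, Krt18, Chac1 and Perp among them, while Hmox1 and Gsr belong to the NRF2 list that fell in the knockout and rose with arsenite. Genes are not independent replicates, so these tests describe the lists and not the samples.

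The comparison of Trim33 knockout with wild type under activin A rests on labels that Trim33 follows. It asked which genes depend on TRIM33 while the SMAD2 and SMAD3 pathway is active. The Y-linked gene Eif2s3y also differed (39.7 RPKM in wild type and 0.0325 in knockout). Another difference between the cell lines than Trim33 therefore cannot be told apart from the knockout. Trim33 fell from 21.8 ± 2.41 to 2.66 ± 0.182 RPKM (SD, n = 2; -2.63 ± 0.18, adjusted p = 2.82e-04). Lefty1 stood at 334 ± 54.2 RPKM in wild type and 219 ± 40.4 in knockout and Lefty2 at 162 ± 48.2 and 84.4 ± 35.8, and neither passed (-0.61 ± 0.33, adjusted p = 0.293, and -0.97 ± 0.55, adjusted p = 0.305). Pml stood at 32.4 ± 4.56 and 21.6 ± 2.00 RPKM and did not pass (-0.56 ± 0.15, adjusted p = 0.0504). When only the 4 activin A libraries were fitted, Lefty1 (adjusted p = 0.0429) and Pml (adjusted p = 0.0313) passed and Lefty2 did not (adjusted p = 0.0532). The largest rises were in BC002163 (0.367 ± 0.172 to 23.9 ± 6.90 RPKM), the autophagy receptor gene Calcoco2 (10.6 ± 0.517 to 155 ± 50.7), Arl14epl (3.66 ± 1.95 to 53.6 ± 8.33), Pramel7, a gene of the early embryo (0.0162 ± 0.0229 to 7.75 ± 4.96), the glycosyltransferase gene Galnt6 (2.91 ± 0.27), the meiotic gene Spata22 (2.72 ± 0.15) and the EGF-family ligand gene Areg, listed at 0 in both wild-type libraries and at 5.58 ± 1.26 RPKM in knockout.

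Among the largest falls beside Trim33 itself were those of the Y-linked genes Eif2s3y, Ddx3y (15.0 ± 1.35 RPKM in wild type and listed at 0 in both knockout libraries) and Uty (3.72 ± 0.123, listed at 0 in both knockout libraries), and of the imprinted non-coding RNA gene Rian (-2.95 ± 0.31). Gapdh (-2.29 ± 0.56, 150 and 55.6 RPKM in the wild-type libraries), AF357359 (-2.09 ± 0.44) and Rps3a1 (-2.03 ± 0.17) were also among them, all with copies or short transcripts to which reads are hard to assign. With no filter on low values Gapdh (adjusted p = 0.101) and AF357359 (adjusted p = 0.0730) lost their call. Gapdh also lost it without any 1 of the 4 activin A libraries (adjusted p = 0.0549 to 0.193), and AF357359 without knockout replicate 1 or either wild-type replicate (adjusted p = 0.0837 to 0.133).

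Of 13 genes of the two-cell-like state, 7 rose (13 adjusted over the list alone). Among them were Gm5662 (2.52 ± 0.35), Gm8300 (1.43 ± 0.24) and Tcstv1 and Zscan4c, which were listed at 0 in both wild-type libraries. These named genes were under 1 RPKM in both wild-type libraries and were tested only because other libraries reached 1. The count of rises in this list is thus partly set by the filter. Camera gave adjusted p = 1.03e-07, and adjusted p = 0.577 with an estimated correlation. Of 11 genes of formative and primed pluripotency, 4 fell (6 adjusted over the list alone): the WNT effector gene Lef1 (-1.47 ± 0.20), the DNA methyltransferase gene Dnmt3b (-0.87 ± 0.12) and the POU factor gene Pou3f1 (-1.44 ± 0.33) led. For this list camera gave adjusted p = 2.24e-04, and adjusted p = 0.256 with an estimated correlation. Of 15 naive pluripotency genes, 4 rose and 1 fell (10 adjusted over the list alone). They included Zfp42 at 1.23 ± 0.20, Tcl1 at 1.18 ± 0.21 and Gbx2 at -1.71 ± 0.24 (camera adjusted p = 0.351). Of 14 hypoxia and glycolysis genes, 6 fell (9 adjusted over the list alone). Examples were Pdk1 at -1.51 ± 0.12, Bnip3 at -0.87 ± 0.15 and Pgk1 at -0.60 ± 0.12. The list had camera adjusted p = 1.13e-04, and adjusted p = 0.256 with an estimated correlation. Of 36 replication-dependent histone genes, 5 rose (11 adjusted over the list alone). Among them were Hist1h4i (1.29 ± 0.19) and Hist1h3a (1.41 ± 0.24). The camera test gave adjusted p = 1.42e-04, and adjusted p = 0.256 with an estimated correlation. Of 13 FGF-ERK targets, 4 fell (7 adjusted over the list alone; camera adjusted p = 0.278), while the list median was 0.05 and the mean -0.18. They included Spred1 at -1.16 ± 0.17 and Dusp6 at -0.76 ± 0.15. None of 11 Nodal and activin targets passed in the fit of all 8 libraries, over all genes or adjusted over the list alone (camera adjusted p = 0.137). With only the activin A libraries 1 was higher and 1 lower, and 6 passed adjusted over the list alone (camera adjusted p = 0.0528), so the result for this list depends on the fit. In the 8-library fit, Nodal was at 0.49 ± 0.14 (adjusted p = 0.0598, and 0.0209 with only the activin A libraries) and Tdgf1 at -0.43 ± 0.13 (adjusted p = 0.0728).

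The limma test called 1123 of 11914 genes, 787 higher and 336 lower, with 367 changed at least 2-fold, and TMM scaling or quantile normalization lowered the share of higher calls from 70.1% to 57.8% or 57.9%. Tcl1, Dusp6 and Pgk1 lost their call without any 1 of the 4 activin A libraries (adjusted p = 0.060 to 0.0992, 0.0548 to 0.128 and 0.0694 to 0.142). Pou3f1, Gm8300, Tcstv1 and Zscan4c lost it without knockout replicate 1 or either wild-type replicate (adjusted p = 0.0698 to 0.199, 0.0569 to 0.0815, 0.0622 to 0.0751 and 0.0694 to 0.0837). Bnip3 lost it without knockout replicate 2 or either wild-type replicate (adjusted p = 0.0614 to 0.0989). Zfp42 lost it without knockout replicate 1 or wild-type replicate 2 (adjusted p = 0.0606 and 0.0789), and Hist1h3a without replicate 2 of either genotype (adjusted p = 0.0608 and 0.0815). Spred1 and Hist1h4i lost it without wild-type replicate 1 (adjusted p = 0.0569 and 0.0567), and Pou3f1 also with no filter (adjusted p = 0.0814). The count was 1852 with only the 4 activin A libraries, and fell to 185, 264, 218 and 355 when replicate 2 or 1 of wild type, or 1 or 2 of knockout, was left out. The overlap with the Pml knockout was tested because the title names both proteins. Of 11125 genes tested in both, 150 rose in both where 111 would be shared by independent lists (odds ratio 1.49, 1.23 to 1.80, Fisher's exact test, two-sided, p = 5.73e-05). In the other direction 85 fell in both where 58.9 would be shared (odds ratio 1.64, 1.25 to 2.12, Fisher's exact test, p = 2.31e-04). Of 483 genes called in both, 235 had the same direction, where 170 would by independent lists, and 248 the opposite one, where 180 would. Both directions were thus shared in excess, and among these genes a relation between the directions did not pass (odds ratio 0.937, 0.632 to 1.39, Fisher's exact test, p = 0.774, a test added after the overlap was seen). By Fisher's exact test the overlap of rises did not pass with no filter on low values (odds ratio 1.26, p = 0.0788). By the same exact test the overlap of falls did not pass with TMM-scaled values (1.25, p = 0.0567) or quantile normalization (1.25, p = 0.0686). The Y-linked Eif2s3y fell in both knockouts (log2 fold changes of -3.33 and -5.30). Ddx3y and Uty, also Y-linked, had lower means in both. How much of the overlap of falls these genes make up was not counted, so that overlap can in part reflect another difference between the cell lines. The odds ratio for falls was larger with no filter (3.13) and with a 2-fold minimum (18.5). Over left-out libraries it ranged from 1.32 to 3.63, so its size depends on the setting.

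The effect of activin A against SB431542 was taken as the mean over both genotype labels, a comparison chosen after the data were seen, because that mean is the same whichever genotype the SB431542 libraries carry. Lefty1 rose from 17.4 ± 9.79 RPKM with SB431542 to 277 ± 77.0 with activin A (SD, n = 4; 4.04 ± 0.24, adjusted p = 5.57e-04). The inhibitory SMAD gene Smad7 rose by 2.40 ± 0.16, the growth factor gene Fgf15 by 2.05 ± 0.15, the sulfotransferase gene Chst15 by 1.76 ± 0.14 and the TGF-beta pathway inhibitor gene Pmepa1 by 1.45 ± 0.15. The Eph receptor gene Epha2 (1.32 ± 0.11), the interferon regulatory factor gene Irf1 (1.30 ± 0.15) and Wnt3 (1.25 ± 0.14) also rose. Lefty2 stood at 34.0 ± 22.5 RPKM with SB431542 and 123 ± 56.8 with activin A and did not pass (1.93 ± 0.39, adjusted p = 0.229). It passed with the replicate number as a block, which called 23 genes where the main fit called 13. The labels do not say that these numbers pair libraries. In the values, each SB431542 library correlated best with the same-numbered activin A library of the other genotype label. Within these pairs Lefty2 read 22.3 and 59.1, 65.2 and 110, 13.7 and 128, and 34.8 and 196 RPKM with SB431542 and activin A. Whether Lefty2 passes thus depends on whether the numbers pair libraries. Lefty1 lies on chromosome 1, positions 180935022 to 180938400, and Lefty2 at 180893108 to 180899103, both on the plus strand with 4 exons, 35.92 kb apart, and 17.89% of the 50-base words of Lefty1 also occur in Lefty2, so reads can be shared.

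Of 11 Nodal and activin targets, 4 rose and none fell (10 adjusted over the list alone), and this list kept its call with an estimated correlation. With camera this gave adjusted p = 8.97e-39, and adjusted p = 0.00470 with an estimated correlation. Of 7 mesoderm and definitive endoderm genes, 1, Wnt3, rose (3 adjusted over the list alone). Its camera adjusted p was 3.19e-07, and adjusted p = 0.0691 with an estimated correlation. In total 13 of 11914 genes passed in limma and all 13 were higher with activin A. The count was 8 with no filter on low values, 6 higher and 2 lower, and 16 without replicate 2 labelled knockout with SB431542, 15 higher and 1 lower, so the single direction did not hold there. It was again 8 without replicate 1 labelled wild type with activin A. It was 7 without replicate 2 labelled knockout with activin A, replicate 2 labelled wild type with activin A or replicate 1 labelled wild type with SB431542. With no filter, Pmepa1 (adjusted p = 0.116), Irf1 (adjusted p = 0.130) and Wnt3 (adjusted p = 0.132) lost their call. Pmepa1 also lost it without replicate 1 labelled wild type with activin A or with SB431542 (adjusted p = 0.0738 and 0.0521). Irf1 lost it without activin A replicate 2 of either label or SB431542 replicate 1 of either label (adjusted p = 0.0536 to 0.0741). Wnt3 lost it without any library other than activin A replicate 1 labelled knockout and SB431542 replicate 2 labelled wild type (adjusted p = 0.0536 to 0.102).

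Read by their labels, the comparisons that use the SB431542 libraries placed Trim33 in opposite directions. In the libraries labelled wild type, activin A against SB431542 called 1351 genes, 464 higher and 887 lower, with Trim33 itself higher (2.62 ± 0.18) beside Lefty1 (4.89 ± 0.33), Lefty2 (2.02 ± 0.55) and Smad7 (2.56 ± 0.22). In the libraries labelled knockout, it called 1248 genes, 856 higher and 392 lower, with Trim33 lower (-2.60 ± 0.18) and Lefty1 (3.18 ± 0.33) and Smad7 (2.24 ± 0.22) higher, while Lefty2 did not pass (1.83 ± 0.55, adjusted p = 0.0678). TMM scaling and quantile normalization moved the share of higher calls from 34.3% to 45.7% and 44.2% under the wild-type label, and quantile normalization from 68.6% to 57.8% under the knockout label. With SB431542, the libraries labelled knockout against those labelled wild type called 1139 genes, 359 higher and 780 lower (31.5% higher, 41.7% with quantile normalization), with Trim33 higher (2.59 ± 0.18), and 8 of 13 two-cell-like genes were called lower in the libraries labelled knockout (13 adjusted over the list alone). For this list camera gave adjusted p = 2.44e-07, and adjusted p = 0.610 with an estimated correlation. Higher and lower would trade places in this comparison if its 2 labels were exchanged. Over the 1351 genes called under the wild-type label, the slope through the origin of the knockout-label response on the wild-type-label response was -0.76. These genes were chosen on the libraries labelled wild type, so regression to the mean can shrink the slope but does not make it negative. Of the 1351 genes, 837 were called under both labels, and 822 of these went in opposite directions and 15 in the same. The interaction tests whether the response differs between the labels as given. If the labels of the SB431542 libraries were exchanged, it would instead add the genotype differences under both treatments and test no difference in response. The interaction test called 3129 genes, 1923 higher and 1206 lower (61.5% higher, 51.0% with TMM scaling and 49.5% with quantile normalization), Lefty1 (-1.71 ± 0.47, adjusted p = 0.0286) and Pml (-1.16 ± 0.21, adjusted p = 0.00486) among them. Since each of these directions is drawn from libraries whose genotype label Trim33 contradicts, none can be read as an effect of genotype or treatment alone. Leaving out single libraries moved these counts by over 1.5 times. Under the wild-type label the count was 373 and 268 without activin A replicates 1 and 2, and 500 and 566 without SB431542 replicates 1 and 2. Under the knockout label it was 230 and 461 without activin A replicates 1 and 2. Between labels with SB431542 it was 294 and 514 without replicates 1 and 2 labelled wild type and 673 without replicate 2 labelled knockout. For the interaction it was 1917 without replicate 1 labelled knockout with activin A, and 2051 and 1853 without replicates 1 and 2 labelled wild type with activin A. The Lefty2 call under the wild-type label (adjusted p = 0.0464) did not hold without either of its activin A libraries (adjusted p = 0.109 and 0.235) or without SB431542 replicate 1 (adjusted p = 0.198). The Lefty1 interaction did not hold with no filter (adjusted p = 0.0753) or without activin A replicate 1 or SB431542 replicate 2 labelled knockout (adjusted p = 0.0792 and 0.0796). Nor did it hold without activin A replicate 1 or 2 or SB431542 replicate 1 labelled wild type (adjusted p = 0.0510, 0.0950 and 0.0637).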

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

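The tests of the SB431542 libraries below were chosen after the results were seen; the interaction was fixed before the data were examined. The response to activin A against SB431542 differed between the genotype labels in 3129 genes by limma's interaction test, with Trim33 at -5.23 and Lefty1 at -1.71 on the log2 scale (knockout label minus wild-type label). If the genotype labels of the SB431542 libraries were exchanged, this contrast would add up genotype differences and not compare responses. Every group had 2 libraries, too few to look for a sample far from the others.

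Trim33 and other genes followed the other genotype label in the SB431542 libraries. A treatment effect on Trim33 alone is argued against by the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d, which differed by a median of 3.07 log2 units between treatments of one genotype label, and a difference in depth by the recovered depths, whose highest was 1.27 times the lowest. A candidate explanation is that the genotype labels of the SB431542 libraries were exchanged: 4 of the 4 libraries correlated best with an activin A library of the other genotype label (0.989 to 0.994, against at most 0.974 with their own), over all tested genes except Trim33 and the Y-linked ones. Whether the exchange would lie in the cultures, the libraries or the column names was not tested, and no biological explanation other than treatment was tested.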

How the results depend on the processing

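The comparison of activin A over both labels, with all its alternatives, was chosen after the data were seen; all other settings were fixed before the data were examined. Of the 171 named gene values, 170 kept direction and side of the threshold with a pseudocount of 0.1, 168 with TMM-scaled values, 169 with quantile normalization, 168 with no trend, 158 with no filter and 164 with the replicate block; 847 of the left-out-library values did, 86 lost and 8 gained a call. With no filter, activin A over both labels called 8 genes and the higher overlap of the knockouts had an odds ratio of 1.26; the lower overlap was 1.25 with TMM-scaled values and 1.25 with quantile normalization. With a 2-fold minimum, which by construction keeps fewer, the counts were 451 (Pml), 876 (arsenite), 445 and 413 (activin A, labels wild type and knockout), 367 and 384 (genotype with activin A and SB431542) and 1983 (interaction). With an estimated correlation 0 lists kept a call for Pml, arsenite and Trim33, and 1 for activin A over both labels (20, 13, 6 and 7 before). The lowest adjusted p of camera was then 0.254, 0.390 and 0.256 for Pml, arsenite and Trim33. With 2 or 4 residual degrees of freedom this version can hardly pass, so the loss of calls decides little. With only the groups compared, counts were 753 (activin A, knockout label), 1852 and 608 (genotype with activin A and SB431542). Same-numbered libraries do not pair by the labels and there are 2 numbers only; their deviations correlated at 0.0234 (Pml), -0.0361 (arsenite) and -0.140 to 0.602 (Trim33), where the third principal component (11.2% of the variance) separated the 2 numbers in all 4 groups. The replicate block gave 4324, 8188, 1806, 1731, 1584, 1557 and 3667 calls for Pml, arsenite, activin A by label (wild type, knockout), genotype (activin A, SB431542) and interaction, and 23 genes, Lefty2 among them (adjusted p = 0.00483), and 13 lists for activin A over both labels. Over left-out libraries, where a lone library is assumed to vary like the others, counts ranged from 2985 to 3895 (Pml), 6420 to 7482 (arsenite), 268 to 1848 and 230 to 1172 (activin A, labels wild type and knockout), 185 to 1546 and 294 to 1036 (genotype with activin A and SB431542), 1853 to 3395 (interaction) and 7 to 16 genes and 5 to 16 lists (activin A over both labels), and the slope from -0.82 to -0.70. No value passed in a setting where its sign changed: Pml in arsenite (0.0084 with quantile normalization, -0.062 to 0.0058 over left-out libraries), and over left-out libraries Trim33 in the Pml knockout (-0.0080 to 0.035), Lefty2 in the interaction (-0.95 to 0.56) and Trim33 for activin A over both labels (-0.091 to 0.11). The cause was not tested for the other changes. The edgeR quasi-likelihood test planned for raw counts was not run, because no table holds counts. Depth limits low genes: 1 RPKM is 31.2 to 48.5 reads per kilobase.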

Other observations

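The tests on marker lists in the Pml knockout below were chosen after the results were seen, and so was the comparison of activin A over both labels on which the test of the splits rests; the test of the trend was fixed before. In the Pml knockout, 10 of 15 cholesterol synthesis genes fell and none rose (11 adjusted over the list alone), with the SREBP regulator gene Insig1 at -0.99 ± 0.08 and the sterol demethylase gene Cyp51 at -0.54 ± 0.07 (camera adjusted p = 5.67e-04, and adjusted p = 0.254 with an estimated correlation). Of 16 imprinted genes, 11 rose and 3 fell (14 adjusted over the list alone), with Impact at 1.11 ± 0.07 and Peg10 at 0.97 ± 0.06 beside Igf2 and Grb10 (camera adjusted p = 3.48e-04, and adjusted p = 0.254 with an estimated correlation). Of 14 germline genes, 8 fell and none rose (9 adjusted over the list alone; camera adjusted p = 0.00840, and adjusted p = 0.368 with an estimated correlation).

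With arsenite the inducible chaperone gene Hspa1a was listed at 1.69 and 1.18 RPKM in untreated cells and 1.71 and 1.64 in treated ones, while most of the heat-shock list rose; 58.81% of the 50-base words of Hspa1a also occur in Hspa1b, so reads can be lost or shared and these values do not show that the gene stayed low. Hand1, a transcription factor gene of trophoblast and mesoderm, and the collagen gene Col1a1 differed within groups of the Trim33 table: Col1a1 read 27.4 and 5.07 RPKM in replicates 1 and 2 labelled knockout with activin A and 22.4 and 3.60 in those labelled wild type with SB431542, and Hand1 read 13.5 and 5.11, and 10.9 and 3.71. Sumo2, which encodes a small modifier protein and has pseudogene copies, read 63.9 and 288 FPKM in the wild-type libraries of the Pml table and 230 and 71.8 in the knockout ones.

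Trophectoderm and fibroblast marker lists were higher in the Pml knockout. For fibroblasts in the cultures, the matrix genes Col1a1, Col1a2, Col3a1, Col5a1, Dcn, Lum and Postn were set against Tagln. Their median FPKM in the knockout was 0.50% of that of Tagln (1.35 against 271). Col1a1 stood at 9.73, Col5a1 at 7.56 and Col3a1 at 4.59. These collagen genes and Col1a2 had higher means in the knockout than in wild type. How much of the Tagln signal came from fibroblasts is unknown, so the ratio does not decide on a small share of fibroblasts. A smaller share of ES cells was taken to raise the markers of every other type alike. Of the 14 tested primitive endoderm and neuroectoderm genes, 7 were called lower and 6 higher. Cells moving toward a single fate would raise only the markers of that fate, so these counts do not decide on a smaller share. Another difference between the cell lines than Pml cannot be told apart from the knockout, since a knockout line is not the wild-type line, and the Y-linked genes differed by a median of -2.12 on the log2 scale. Altered regulation in the ES cells labelled Pml knockout is a hypothesis that was not tested.

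The calls shared by the Pml knockout and arsenite may come from a common trend over genes. The correlation across genes of their fold changes was 0.343, and 0.352 after correction of both for transcript length, GC content and mean expression (10780 genes, 96.6% of those tested in both), which argues against such a trend; genes are not independent replicates. A shared response of ES cells to both conditions stays open.

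For activin A against SB431542 over both labels, chance could not be excluded by the count of calls alone: 2 of the 35 splits of the 8 libraries into 4 and 4 gave as many, the real one included. The fit had 2 groups, so the difference between the genotype labels stayed in its residual spread, and it called 4 genes for the real split. The highest other split called 3915 and joined the libraries labelled knockout with activin A to those labelled wild type with SB431542, which points to a structure of the samples. That split alone set the share, so the test decides little about chance. The count does not bear on single genes: Lefty1 was at 191 RPKM or more in each activin A library and at 30.6 or less in each SB431542 library.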
